A study of Mus musculus with 2 samples.

How the data were processed

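Single-cell RNA counts of CD45+-sorted spleen cells from 2 libraries were analysed, 1 from the Vehicle group and 1 from the Glutoborin group, as assigned by the treatment given in the labels. How many mice each library holds is not given in the sources used here. The deposited matrices hold whole-number UMI counts per gene and barcode, with no normalization, and each barcode in them has at least 500 UMIs. The matrices were written by Cell Ranger 6.1.2 per the file headers, whereas Cell Ranger 6.0.1, Seurat 4.3.0 and the mm10 genome are listed in the submitters' processing notes. The annotation release is not given in the sources used here. Of 32285 genes in the deposited feature lists, 32235 (99.8%) had their identifier in GENCODE release 21 of the mouse annotation on GRCm38, the assembly also called mm10, from which gene positions were taken. Both libraries were male by their transcripts: Xist had 1 and 3 UMIs, and the Y-linked Ddx3y 3277 and 4248, in Vehicle and Glutoborin.

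Cells were kept with at least 300 detected genes, at least 500 UMIs and under 10% mitochondrial UMIs, which left 6688 Vehicle and 9253 Glutoborin barcodes. Doublets were called by Scrublet (as built into scanpy) in each library alone with its automatic threshold and left out: 196 in Vehicle (2.93%) and 386 in Glutoborin (4.17%). The kept cells were 79.1% of the Vehicle and 91.9% of the Glutoborin barcodes, with medians of 5688 and 4806 UMIs. The 1515 Vehicle and 393 Glutoborin barcodes at or over 10% mitochondrial UMIs had medians of 1085 and 910.0 UMIs.

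Both libraries were clustered together without batch correction. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1.5 were used. Antigen receptor segments, mitochondrial, ribosomal, haemoglobin and sex-linked genes, and the interferon, cell cycle, heat shock and immediate early lists, were left out of the variable genes, so that these lists could be compared between groups. T cell clusters were clustered again in the same way. Clusters were named from markers of 23 cell classes, and a class name stands for cells that resemble that type (B-cell-like, monocyte-like and so on). A cluster needed at least 3 markers of its class, each detected in at least 20% of its cells. It stayed unnamed where its leading 10 genes by fold pointed elsewhere. The same held where core genes of more than 1 lineage were each detected in at least 40% of its cells. Finer T classes also needed Cd4, Cd8a, Foxp3 or Trdc in at least 40% of cells. These naming limits were set after the clusters were seen. Clusters 15, 16, 21, 25, T14 and T17 stayed unnamed. Cluster 15 held 1.83% of Vehicle and 1.73% of Glutoborin cells, cluster 16 held 1.57% and 1.48%, cluster 21 held 0.955% and 0.733%, cluster 25 held 0.416% and 0.113%, T14 held 0.647% and 0.677%, and T17 held 0.431% and 0.293%. Classes with at least 100 cells in each library were compared: B cells, CD4, CD8 and regulatory T cells, NK cells and monocytes.

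For each class the UMIs were summed per library and divided by the class total to give CPM, UMIs per 1000000. The summed totals were 18926007 and 24158849 UMIs for B cells in Vehicle and Glutoborin, 4738964 and 5551547 for CD4 T cells, 5592666 and 7527980 for CD8 T cells, 2168294 and 2200997 for NK cells, 3265741 and 2295621 for monocytes, and 809518 and 829631 for regulatory T cells. Shares of cells carry exact binomial (Clopper-Pearson) intervals, sums carry exact Poisson intervals, and ratios of a pair of counts carry the exact interval of the ratio of Poisson counts, all at the 95% level. Because each group is 1 library, no test was run and no p-value is given. For shares of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. Beside a share of 0, the limit given is 3 counts of the thinned cells, in place of the exact interval, and it covers cells with a UMI at that depth alone.

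The 30 gene lists, the cell markers, the filters, the exact intervals and the rule for named genes were chosen before the data were examined. List members with at least 50 UMIs over both libraries were measured, and lists with at least 5 measured members in a class were described by their median log2 ratio, by the number of members at least 1.5-fold higher or lower, and by the percentile of the median among 10000 random lists matched on mean expression in 20 bins. Intervals of list medians, added after the data were seen, come from 1000 Poisson redraws of the counts, and those of ratios of differences from 2000. List and marker symbols with no match among the feature symbols were not analysed here. Under the rule for named genes, genes with at least 50 UMIs in a class and at least 50 CPM in the higher library were ranked by the interval bound nearest to no change. The 10 highest on each side were named in B, CD4 and CD8 T cells and the 5 highest in the other classes, or fewer where the bound did not pass 1.2-fold. Antigen receptor, mitochondrial, ribosomal, haemoglobin and sex-linked genes, genes with only a placeholder symbol and markers of other cell lineages were left out of this ranking. For each described list, 2 to 4 members with the largest ratios were named as well, and genes outside these rules were chosen after their values were seen (the transcripts of other lineages Igkc, Lyz2, Jchain, Cd74, Cd3e and S100a9, the genes shared by all 6 classes, and the further list members given with their values).

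The intervals and lists were tested on counts simulated from the Poisson model that the intervals themselves assume. Such counts hold no spread between cells beyond counting error. The shares below therefore check the calculation and do not cover genes whose UMIs lie in a few cells. In simulated B cells 95.5% of 10472 intervals held the true ratio, 0.0584% of 10274 unchanged genes had a bound beyond 1.2-fold, and of the changed genes 71.2% of 66 at 1.5-fold, 86.4% of 66 at 2-fold and 100% of 66 at 4-fold did. In simulated regulatory T cells the shares were 95.5% of 3974 intervals, 0.265% of 3779 unchanged genes, and 26.0% of 73 at 1.5-fold, 75% of 60 at 2-fold and 100% of 62 at 4-fold. Of 200 unchanged lists, 4.5% in B cells and 5% in regulatory T cells lay outside the middle 95% of random lists.

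Alternatives covered doublets kept, mitochondrial limits of 5% and 25%, stricter limits of 800 genes and 1500 UMIs, all variable genes, genes centred within each library, resolution 0.8, median-of-ratios scaling, totals without immunoglobulin, haemoglobin, mitochondrial and ribosomal genes, equal weight for every cell, thinning, list minimums of 1 and 200 UMIs, all T clusters together, lists without their 10 richest cells or without marker genes, and NK cells with those of a mixed cycling cluster. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.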

Results

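Spleen immune cells of wild-type mice were profiled 5 days after an intraperitoneal injection of 10000 iRBCs, an abbreviation that the labels leave unexplained. The mice had received either Vehicle or Glutoborin, a compound that the labels do not describe further, on days 2 and 4. CD45+ cells, the leukocyte fraction, were sorted and sequenced as droplet single-cell libraries, with 1 library per group. The Vehicle library held 8204 barcodes with 48526451 UMIs (unique molecular identifiers, counting RNA molecules) and a median of 5020.5 UMIs per barcode. The Glutoborin library held 9646 barcodes with 56862506 UMIs and a median of 4792. After filtering, 6492 Vehicle and 8867 Glutoborin cells were kept, with 44148828 and 52140762 UMIs. The filter on mitochondrial UMIs removed unequal shares: 18.5% of the Vehicle barcodes (95% interval 17.6 to 19.3%) reached 10% mitochondrial UMIs, against 4.07% (3.69 to 4.49%) of the Glutoborin barcodes. The comparison asks how the spleen's immune cells differed between the animals given Vehicle and those given Glutoborin. With 1 library per group no test was possible and no spread between animals could be measured. All intervals are exact 95% intervals that cover counting error alone, except those of list medians and of ratios built from several sums or differences, which come from redrawn counts and cover the same error. Log2 ratios are Glutoborin over Vehicle throughout.

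Monocytes made up a smaller share of the sorted cells in the Glutoborin library and neutrophils a larger share, while the lymphocyte classes held similar shares in both. Monocytes, recruited phagocytes of the blood, were 4.57% (4.08 to 5.11%) of Vehicle cells and 2.27% (1.97 to 2.60%) of Glutoborin cells, a log2 ratio of -1.01 (-1.28 to -0.75). Neutrophils were 0.339% of Vehicle cells, from 22 cells, and 0.677% of Glutoborin cells, from 60 cells, a log2 ratio of 1.00 (0.27 to 1.77). In the monocyte class the neutrophil gene S100a9 held 1305 Vehicle and 175 Glutoborin UMIs, with 96.8% and 88% of them in 10 cells. Neutrophils placed in that class were not counted. B cells, the antibody-producing lineage, were 53% (51.8 to 54.2%) in Vehicle and 56.5% (55.4 to 57.5%) in Glutoborin. CD4 T cells were 12.3% and 12.6%, CD8 T cells 10.8% and 11.4%, regulatory T cells 2.00% and 1.75%, and NK cells 3.67% and 3.60%. The ratio of CD4 to CD8 T cells was 1.14 (1.03 to 1.26) in Vehicle and 1.10 (1.01 to 1.199) in Glutoborin. Red pulp macrophages, which clear aged red cells in the spleen, were 1.06% and 0.835%, and plasma cells 0.169% and 0.271%, from 11 and 24 cells. Type 2 dendritic cells were 1.34% and 1.22%, type 1 dendritic cells 0.139% and 0.214%, plasmacytoid dendritic cells 0.385% and 0.282%, mature dendritic cells 0.478% and 0.429%, and gamma-delta T cells 0.108% and 0.124%. The smallest of these classes depend on the clustering: at resolution 0.8 type 1 dendritic cells were 1.602% and 1.45%, with the log2 ratio at -0.14 in place of 0.63, and gamma-delta T cells 0.955% and 1.06%. T cells placed in no finer class were 3.70% of Vehicle and 2.90% of Glutoborin cells, and 1 of their clusters, T16, lay mostly in the Vehicle library (0.924% against 0.0789% of cells). Clusters kept out of every class held 5.85% of Vehicle and 5.02% of Glutoborin cells, but 0.847% and 0.361% at resolution 0.8 and 4.203% and 2.02% with a mitochondrial limit of 25%. These shares follow the CD45+ sort and the mitochondrial filter, which removed more Vehicle barcodes, and the class names rest on rebuilt clusters.

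**Figure D1:**
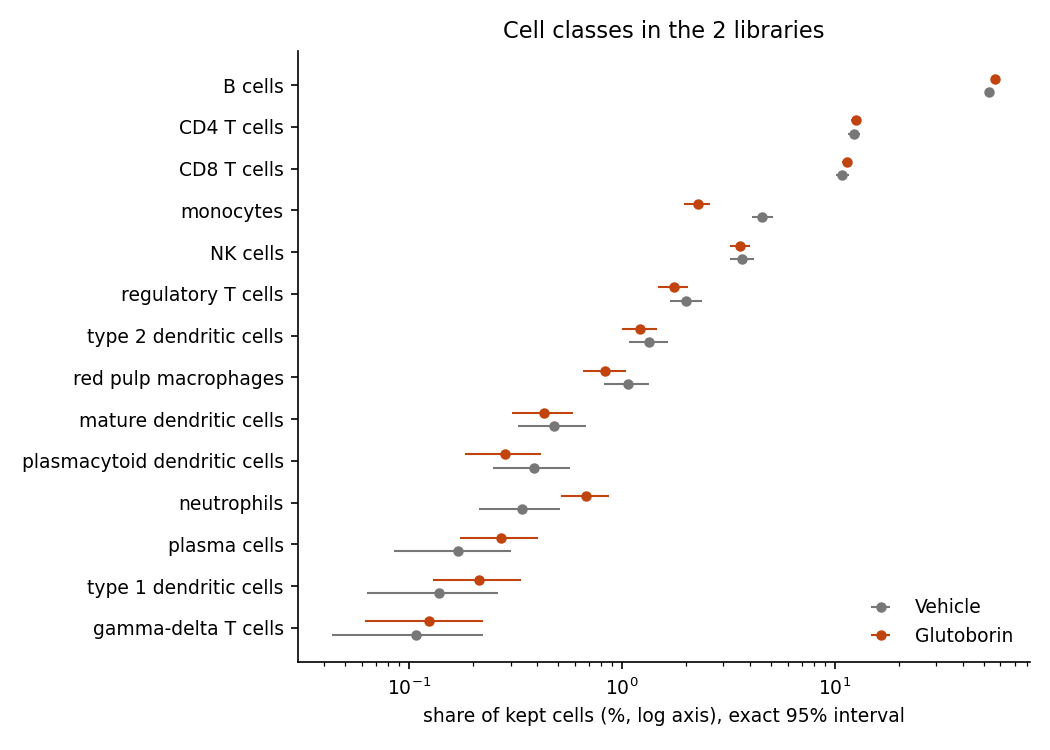
Share of kept cells in each class (percent, log axis) in the Vehicle library (grey) and the Glutoborin library (orange), with exact 95% binomial intervals as bars. Monocytes lie at 4.57% and 2.27%, and neutrophils at 0.339% and 0.677%.

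Genes induced by type I interferon, the family of antiviral cytokines that act through the receptor Ifnar, were lower in the Glutoborin library in each of the 6 classes large enough to compare. In B cells 42 of 45 measured members of this list were at least 1.5-fold lower and the median log2 ratio was -1.51 (-1.54 to -1.43). The median was -1.06 (-1.11 to -0.96) in monocytes with 40 of 46 members lower, -0.78 (-0.86 to -0.74) in CD8 T cells with 35 of 43, -0.77 (-0.82 to -0.71) in CD4 T cells with 31 of 44, -0.70 (-0.86 to -0.58) in NK cells with 21 of 35, and -0.48 (-0.57 to -0.35) in regulatory T cells with 13 of 35. In none of these 6 classes was a member 1.5-fold higher. Genes induced by interferon gamma, the cytokine that T and NK cells release, were lower too: the median was -1.21 (-1.26 to -1.16) in B cells with 24 of 26 members at least 1.5-fold lower, -0.60 in CD4 T cells with 12 of 23, -0.59 in monocytes with 14 of 27, -0.47 in NK cells with 6 of 21, -0.44 in CD8 T cells with 6 of 23, and -0.35 in regulatory T cells with 2 of 22. Each of these 12 medians lay at percentile 0 among 10000 random lists of matched expression, a description of these libraries and not a test. Across all genes of a class, the median log2 ratio lay between -0.05 and 0.02. In the same direction, transcripts that T cells do not make were higher in the Vehicle library: in CD4 T cells the immunoglobulin light chain Igkc stood at 602 CPM (UMIs of a gene per 1000000 UMIs of the class) in Vehicle and 270.0 CPM in Glutoborin, the myeloid lysozyme Lyz2 at 90.5 and 35.5 CPM, and the antibody joining chain Jchain at 28.9 and 5.94 CPM. Igkc was detected in 765 of 801 Vehicle and 802 of 1113 Glutoborin CD4 T cells, unthinned, where 10 cells held 4.03% and 4.40% of its UMIs, against 29.3% and 12.8% in NK cells.

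**Figure D2:**
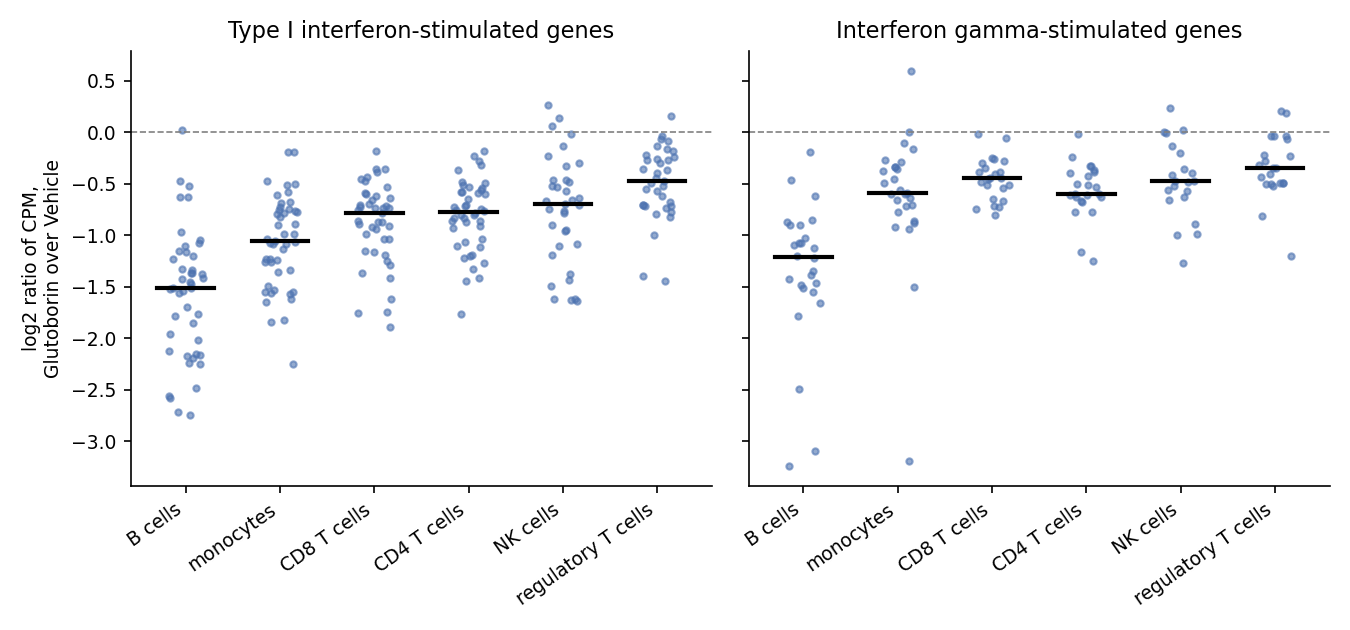
Log2 ratio of CPM, Glutoborin over Vehicle, for each measured member (points) of the type I interferon list (left) and the interferon gamma list (right) in 6 cell classes, with the list median as a bar. The medians of the type I list run from -1.51 in B cells to -0.48 in regulatory T cells.

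Among the genes whose ratio was bounded away from 1 most clearly, the same interferon-induced genes led several classes. Ifit3, an RNA-binding antiviral protein (ENSMUSG00000074896, GRCm38 chromosome 19, 34583531 to 34588731, plus strand), stood at 143 CPM in Vehicle and 24.0 CPM in Glutoborin B cells. Isg15, a ubiquitin-like modifier (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818, minus strand), stood at 159 and 34.8 CPM in B cells. Their log2 ratios in CD4 T cells were -1.42 and -1.201, and in CD8 T cells -1.29 and -1.19. In all 6 classes the interval of the ratio lay beyond 1.2-fold lower in Glutoborin for Ifit1, Isg15, Irf7, Ifi27l2a, Rnf213, Trim30d, Pml and the heat shock protein Hsph1.

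In B cells the interferon-induced genes were the leading group among those lower in Glutoborin. Rsad2, the antiviral enzyme viperin, had a log2 ratio of -2.74 (-3.03 to -2.46), from 628 Vehicle and 120 Glutoborin UMIs. Ifit1 was at -2.71 (-2.95 to -2.48), Ifit3 at -2.58 (-2.71 to -2.45) and Isg15 at -2.19 (-2.31 to -2.08). Ifitm3, a membrane protein that blocks viral entry, was at -2.16, the Isg15 protease Usp18 at -2.17, Slfn5 at -1.96, Oasl2 at -1.85, Rtp4 at -1.78, and Irf7, the transcription factor that amplifies type I interferon, at -1.70. The interferon gamma-induced GTPase Iigp1 was at -1.78 and the ubiquitin ligase Rnf213 at -1.64. The chemokines Cxcl10 and Cxcl9 were at -3.24 and -3.09, on 266 against 36 and 60 against 9 UMIs. These are low counts: in the same Vehicle and Glutoborin B cells the T cell transcript Cd3e held 189 and 146 UMIs. The neutrophil transcript S100a9 held 496 and 353. RNA from other cells was not told apart as a source of the Cxcl10 and Cxcl9 counts. The list of MHC class I presentation genes had a median of -0.32 (-0.41 to -0.26) with 3 of 19 members at least 1.5-fold lower, led by its activator Nlrc5 at -0.89 and the proteasome regulator Psme2 at -0.59.

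Myc, Cd69 and Atf3 were lower in Glutoborin B cells, while most activation and germinal centre genes differed by less than 1.5-fold. Myc, a driver of lymphocyte growth, had a log2 ratio of -0.94 (-1.03 to -0.85), the early activation marker Cd69 -0.79 (-0.85 to -0.74), and the stress-induced factor Atf3 -1.59 (-2.03 to -1.16). The germinal centre genes Mef2b and Rgs13 stood at 0.74 on 45 and 96 UMIs and 0.71 on 57 and 119 UMIs. The whole list of activation and germinal centre genes had a median of -0.18 with 2 members at least 1.5-fold higher and 3 lower of 25. Immediate early genes were at -0.31 with 3 of 18 lower, heat shock genes at -0.43 with 3 of 10 lower, led by Hspa1b at -1.37, and lipid and cholesterol synthesis genes at -0.29 with 1 of 20 lower. After each cell was thinned to 2000 UMIs, Cd69 was detected in 38.6% (37.0 to 40.3%) of Vehicle and 24.9% (23.7 to 26.1%) of Glutoborin B cells, against 11.5% and 4.98% of monocytes. Unthinned, these shares were 60.9% and 40.8% of B cells, of median depth 4685 and 4072 UMIs, and 35.7% and 15.9% of monocytes, of median depth 11484 and 11422 UMIs. The thinning left out 64 Vehicle and 58 Glutoborin B cells, and 11 and 0 monocytes. Fas, a death receptor, was detected in 2.34% and 1.52% of thinned B cells (5.49% and 3.32% unthinned), below its 9.09% and 6.97% in monocytes (34.7% and 29.4% unthinned), and the proliferation marker Mki67 in 0.296% and 0.303% (0.843% and 0.679% unthinned), beside 0.35% and 0.995% of monocytes (3.70% and 3.48% unthinned).

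The genes higher in Glutoborin B cells changed by less. Id3, an inhibitor of E-protein transcription factors (ENSMUSG00000007872, chromosome 4, 136143497 to 136145755, plus strand), stood at 71.3 CPM in Vehicle and 131 CPM in Glutoborin, a log2 ratio of 0.88 (0.79 to 0.97). Next came Trim7 at 0.66, Emp3 at 0.63, the B cell receptor assembly protein Vpreb3 at 0.59, Unc119 at 0.52, Pxdc1 at 0.51, the cold-inducible RNA-binding protein Cirbp at 0.50, Trim5 at 0.48, Crip1 at 0.43 and Fcer2a, the low-affinity IgE receptor CD23, at 0.42. MHC class II genes had a median of 0.18 (0.14 to 0.19) with none of 11 members past 1.5-fold, and the largest ratios were 0.22 for both H2-Aa and H2-Ab1. B cells were spread differently over the clusters in the libraries: cluster 6 held 25.1% of Vehicle and 5.15% of Glutoborin B cells, cluster 2 held 9.82% and 21.4%, and cluster 4 held 7.38% and 18.3%. Transcripts of other lineages went the other way: neutrophil granule genes had a median of -1.24 in B cells with 5 of 7 lower, and Lyz2 stood at 103 CPM in Vehicle and 36.1 CPM in Glutoborin.

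In CD4 T cells, as in B cells, interferon-induced genes and Cd69 were lower in Glutoborin. Rsad2 had a log2 ratio of -1.77 (-2.25 to -1.30), Oasl1 -1.45, Ifit3 -1.42 (-1.596 to -1.24), Oasl2 -1.33, Ifit1 -1.22, Isg15 -1.201 and Rnf213 -1.10. Smaller ratios were found for Herc6, the ligase that attaches Isg15, at -0.93, Trim30a at -0.86, Cd69 at -0.86, Bst2 (tetherin, which holds budding virus) at -0.83, and Ifi27l2a at -0.81, the last from 2665 CPM in Vehicle and 1523 CPM in Glutoborin. Of the interferon gamma list, Cxcl10 was at -1.25, the serpin Serpina3g at -1.16, the guanylate-binding protein Gbp2 at -0.78 and Cd274, which encodes PD-L1, at -0.78. The genes higher in Glutoborin under the naming rule were 6: Gstp3 at 0.63, Ifi27 at 0.56, Lfng, a glycosyltransferase of the Notch pathway, at 0.50, Cirbp at 0.50, Anapc11 at 0.49 and the T cell surface protein Thy1 at 0.45. The lists of T helper 1 genes (0.13), follicular helper genes (0.00), inhibitory receptors (0.12), naive and memory genes (-0.04) and S phase genes (0.01) had median log2 ratios near 0, with at most 1 member of each past 1.5-fold in either direction. Immediate early genes were at -0.22 and MHC class II genes, which are B and myeloid transcripts, at -0.42 with 4 of 10 lower. Cluster T1 held 28.6% of Vehicle and 19.3% of Glutoborin CD4 T cells, and cluster T0 held 26.3% and 39.5%.

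CD8 T cells of the Glutoborin library held more transcripts of cytotoxic effector genes, together with fewer of interferon-induced genes. Of 19 measured cytotoxic genes 9 were at least 1.5-fold higher and 0 were 1.5-fold lower, with a median log2 ratio of 0.32 (0.30 to 0.67). The granule protease Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260, minus strand) stood at 12.2 CPM in Vehicle and 64.2 CPM in Glutoborin, a log2 ratio of 2.40 (2.03 to 2.79). Gzmk was at 2.46 (1.4997 to 3.58) on 10 and 74 UMIs, Gzma at 1.88 (1.67 to 2.09) on 225 and 1115 UMIs, and the calcium-binding protein S100a6 at 1.65 (1.46 to 1.84). Ccl5, a chemokine of memory CD8 T cells, stood at 488 and 962 CPM, a log2 ratio of 0.98 (0.92 to 1.04), and the NK-type receptors Klrc1 and Klrk1 at 1.37 and 1.30. Ifng went the other way, at -0.47 (-0.99 to 0.04). A few cells held most granzyme UMIs: the 10 richest cells held 85.9% of the Glutoborin Gzmb UMIs and 76.5% of the Vehicle ones, 78.9% and 42.7% for Gzma, and 93.2% of the Glutoborin Gzmk UMIs, against 28.5% and 40.6% for Ccl5. After thinning, Gzmb was detected in 1.69% (0.985 to 2.69%) of Glutoborin and 1.14% (0.494 to 2.24%) of Vehicle CD8 T cells, of median depth 6739 and 7408 UMIs, beside 0.202% and 0.740% of B cells, of median depth 4072 and 4685 UMIs. Unthinned these shares were 4.45% and 3.69% of CD8 T cells and 0.539% and 1.74% of B cells, and thinning left out 4 and 3 CD8 T cells.

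Other genes higher in Glutoborin CD8 T cells were the galectin Lgals1 at 0.72, Pkp3 at 0.65, Ctla2a at 0.65, Gstp3 at 0.60, Id3 at 0.57, Ifi27 at 0.47 and Crip1 at 0.40. Among T helper 1 genes 3 of 17 were at least 1.5-fold higher, including Ccl5 and the chemokine receptor Ccr2 at 0.99, with a list median of 0.13. The cyclin Ccnb2 was at 3.09 (1.64 to 5.03) on 4 and 46 UMIs and the mitotic ubiquitin-conjugating enzyme Ube2c at 2.77 on 5 and 46 UMIs, while the median of all 10 measured G2 and M phase genes was 0.07. S phase genes had a median of -0.24 with 4 of 24 lower, and heat shock genes -0.29 with none of 9 past 1.5-fold. Of the interferon-induced genes, Oas1a, a sensor of double-stranded RNA, was at -1.89, Rsad2 at -1.76, Ifitm3 at -1.74, Oas2 at -1.62, Oasl2 at -1.36, Ifit3 at -1.29, Isg15 at -1.19, Ifit1 at -1.16, Rnf213 at -1.14, the exonuclease Isg20 at -1.03, Oas3 at -0.99, Slfn5 at -0.89, Rtp4 at -0.88, and Zbp1, a sensor of Z-form nucleic acids, at -0.87. Of the interferon gamma list, Gbp6 was at -0.81 and Gbp2 at -0.74. Cxcr3, a chemokine receptor of effector T cells, was detected in 4.99% of Vehicle and 5.06% of Glutoborin CD8 T cells after thinning (13.9% and 14.9% unthinned), beside 0.237% and 0.202% of B cells (0.552% and 0.739% unthinned), and Ifng in 1.28% and 0.992% (4.69% and 3.26% unthinned), beside 0.385% and 0.101% of B cells (0.901% and 0.38% unthinned). Pdcd1, which encodes PD-1, was detected in 0 of 701 and 0 of 1008 thinned CD8 T cells, which allows shares of up to 0.428% and 0.298%, and in 0.284% and 0.395% of unthinned cells. Cluster T7 held 25.9% of Vehicle and 9.39% of Glutoborin CD8 T cells, and cluster T2 held 17.6% and 24.1%. Igkc stood at 467 and 213 CPM in this class.

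Regulatory T cells, a class of 130 Vehicle and 155 Glutoborin cells, had lower S phase and interferon-induced genes in Glutoborin. The tubulin-binding protein Stmn1, high in dividing cells, was at -3.36 (-4.86 to -2.15) on 60 and 6 UMIs, with 95% of the Vehicle and 100% of the Glutoborin UMIs in 10 cells. The proliferation marker Mki67 was detected in 0 of 124 Vehicle cells after thinning, which allows up to 2.42%, and in 5 of 152 Glutoborin cells, 3.29% (1.08 to 7.51%), against 0.769% and 5.16% unthinned, beside 0.296% and 0.303% of thinned B cells. S phase genes had a median of -0.60 (-1.10 to -0.32) with 5 of 9 at least 1.5-fold lower, led by the replication helicase subunits Mcm6 at -1.46 and Mcm3 at -1.39, followed by Dut at -1.13 and Mcm7 at -0.999. Mki67 thus went the other way from these genes. The S phase median was not recomputed without the cells richest in the list or with cycling cells of other clusters. Ctsa was at -1.75, Ly6c2 at -1.65 and Ifitm3 at -1.45. Transcripts of other lineages were lower too: Lyz2 stood at 104 CPM in Vehicle and 28.9 CPM in Glutoborin (-1.84), Igkc at 574 and 299 CPM (-0.94), Jchain at -2.17 and Cd74 at -0.83. Higher in Glutoborin were Hivep3 at 1.52, Bscl2 at 1.13, Hcfc1r1 at 0.96, the granule protein Nkg7 at 0.89 and the non-coding RNA Gas5 at 0.51. The list of regulatory T cell genes had a median of -0.11 with none of 11 past 1.5-fold, and its largest ratio was -0.58 for the inhibitory receptor Ctla4. Foxp3, the lineage factor of these cells, was detected in 46.8% (37.8 to 55.9%) of Vehicle and 37.5% (29.8 to 45.7%) of Glutoborin cells after thinning, of median depth 5321 and 4871 UMIs, beside 0.0888% of Vehicle B cells and 0 of 4948 Glutoborin B cells, which allows up to 0.0606% (0.174% and 0.0799% unthinned). The unthinned shares were 68.5% and 56.1%, and 6 and 3 cells were left out. Cxcr3 was detected in 2.42% and 7.89% after thinning (8.46% and 16.1% unthinned), from 3 and 12 cells.

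NK cells of the Glutoborin library held fewer transcripts of DNA replication and cholesterol synthesis genes. Of 27 measured S phase genes 25 were at least 1.5-fold lower, with a median log2 ratio of -1.27 (-1.37 to -1.09), at percentile 0 among random lists. The chromatin remodeller Hells (ENSMUSG00000025001, chromosome 19, 38930915 to 38971051, plus strand) was at -2.00 (-2.52 to -1.50), the replication licensing factor Cdc6 at -1.99, Rrm2, a subunit of ribonucleotide reductase, at -1.91 and the uracil glycosylase Ung at -1.68. Pclaf, a partner of the sliding clamp Pcna, was at -1.99, with 79.3% of its Vehicle and 93.6% of its Glutoborin UMIs in 10 cells, against 42.4% and 71.4% for Hells. G2 and M phase genes had a median of -0.65 (-0.94 to -0.30) with 5 of 9 lower, led by Cdk1 at -1.21, Birc5 at -1.14 and Top2a at -1.02. Lipid and cholesterol synthesis genes had a median of -0.77 (-1.10 to -0.52) with 9 of 13 lower, led by farnesyl diphosphate synthase Fdps at -2.07 (-2.64 to -1.54), Cyp51 at -1.81 and Idi1 at -1.63. Heat shock genes were at -0.60 with 6 of 9 lower, constitutive proteasome subunits at -0.29 with none of 31 past 1.5-fold, and antibody secretion and unfolded protein genes at -0.35 with 4 of 18 lower, led by Creld2 at -0.79 and Hspa5 at -0.78.

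The effector genes of NK cells moved both ways. Ifng was at -0.75 (-0.92 to -0.58) and Gzmb at -0.74 (-0.83 to -0.64), while Gzmk was at 1.201, Gzmm at 0.91 and Ccl5 at 0.69, so that the cytotoxic list had a median of 0.02 with 3 higher and 3 lower of 24. Higher in Glutoborin were Stard10 at 1.82 (1.249 to 2.42), Ypel3 at 1.36, the surface glycoprotein Cd7 at 1.33 (1.19 to 1.46) from 292 to 731 CPM, the transcription factor Zbtb20 at 1.02 and the activating Ly49-family receptor Klra4 at 0.89. The lymphoid transcription factors Lef1 and Tcf7 stood at 1.05 and 1.03 and Cxcr3 at 0.88. Ifi27l2a at -1.64, Ifit1 at -1.63, Ifitm3 at -1.62 and Ly6a, the surface antigen Sca-1, at -1.62 were the lowest of the type I interferon list. NK cells were deeper in the Vehicle library, with a median of 8238 UMIs against 6408. MHC class II genes were at -0.76 with 5 of 9 lower and Igkc stood at 649 and 251 CPM.

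**Figure D3:**
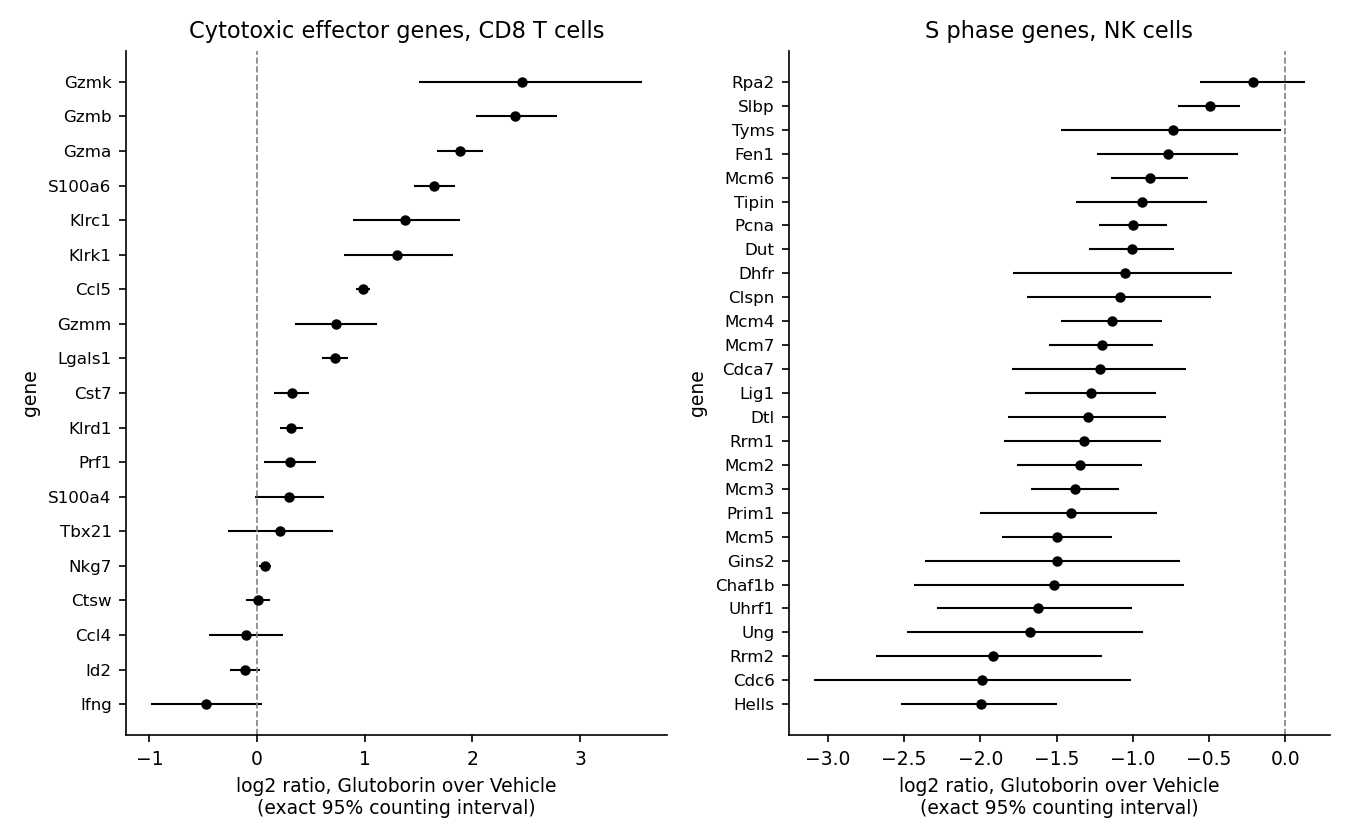
Log2 ratio of CPM, Glutoborin over Vehicle, with exact 95% counting intervals, for 19 cytotoxic effector genes in CD8 T cells (left) and 27 S phase genes in NK cells (right). Gzmb lies at 2.40 in CD8 T cells and Hells at -2.00 in NK cells.

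Monocytes of the Glutoborin library had fewer inflammatory chemokine, heat shock and interferon-induced transcripts, and more of Fn1, Apoc2, Trem2, Cd93 and Pltp. Fn1, which encodes fibronectin (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200, minus strand), stood at 367 CPM in Vehicle and 979 CPM in Glutoborin, a log2 ratio of 1.42 (1.32 to 1.52). The apolipoprotein Apoc2 was at 1.39, the lipid receptor Trem2 at 1.30, Cd93 at 1.30 and the phospholipid transfer protein Pltp at 1.24. Cxcl9, a chemokine induced by interferon gamma, was at -3.19 (-3.51 to -2.88), with 95.8% of its Vehicle UMIs and 100% of its Glutoborin UMIs in 10 cells. Myeloid cytokines and chemokines had a median of -0.72 (-0.94 to -0.53) with 10 of 18 lower and 2 higher, including the prostaglandin synthase Ptgs2 at -2.17, Cxcl10 at -1.51 and the interleukin receptor antagonist Il1rn at -1.44. Heat shock genes were at -0.57 with 6 of 12 lower, led by Hspa1b at -2.75, Hspa1a at -1.89 and Hspa8 at -1.12. Of the interferon-induced genes, Ifi208 was at -2.25, Slfn4 at -2.14, Ifi44 at -1.84 and Ifit2 at -1.82. MHC class I genes were at -0.41 with 7 of 19 lower, led by H2-Q6 at -1.05. The list of red cell uptake and iron handling genes had a median of 0.23 (0.08 to 0.31) with 2 of 14 higher and 2 lower: the complement component C1qb was at 1.65 on 24 and 53 UMIs, Trf at 0.63, the haem oxygenase Hmox1 at -0.97 and the receptor kinase Axl at -0.94. Oxidative phosphorylation genes were at 0.15 with none of 28 past 1.5-fold. Transcripts of other cell types moved too: naive and memory T genes were at -0.70 with 8 of 16 lower, Cd3e stood at 36.7 and 16.1 CPM with 50% and 89.2% of its UMIs in 10 cells, and the neutrophil gene S100a9 was at -2.39 with 96.8% of its Vehicle UMIs in 10 cells.

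**Figure D4:**
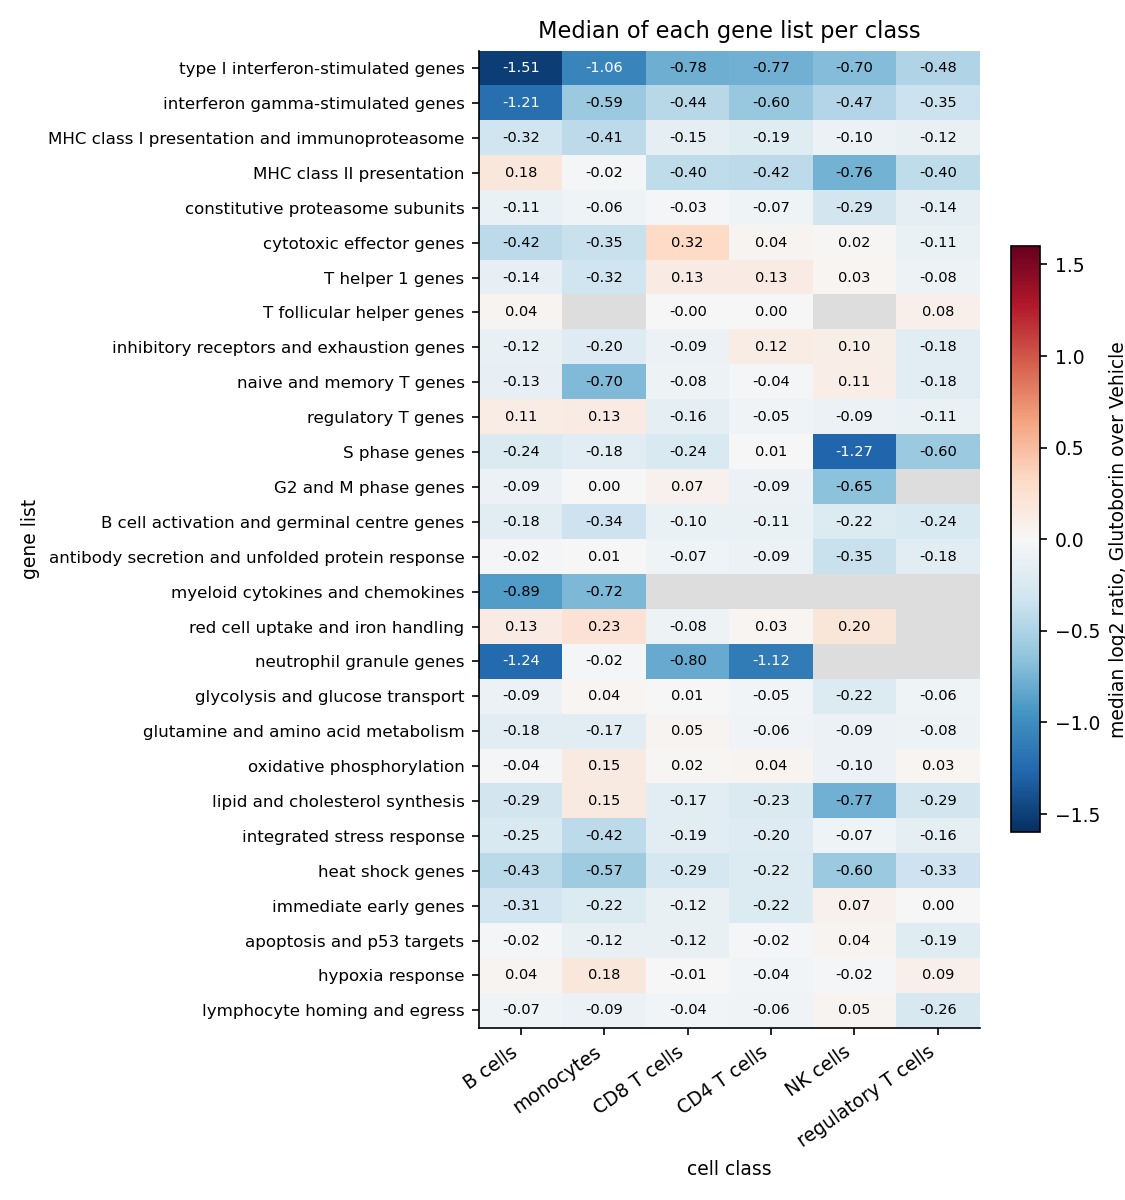
Median log2 ratio, Glutoborin over Vehicle, of each fixed gene list (vertical axis) in 6 cell classes (horizontal axis), with blue for lower and red for higher in Glutoborin and grey where fewer than 5 members were measured. The type I interferon list is negative in all 6 classes, from -1.51 to -0.48, and the S phase list is at -1.27 in NK cells.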

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

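The tests of free RNA of NK cells were chosen after the result was seen, and the bounds of the others were set before their values were computed. The cytotoxic effector list went in opposite directions in different classes: its median log2 ratio was 0.32 in CD8 T cells, -0.42 in B cells and -0.35 in monocytes. This difference between classes was not tested, since each group is 1 library. In B cells 5 of 17 members were at least 1.5-fold lower, led by Gzmb at -1.45 and S100a4 at -1.39. In monocytes 5 of 12 were, led by Nkg7 at -2.11 and Klrk1 at -1.46, on transcripts that these cells hold in small amounts. Transcripts of other lineages were lower there as well. Cd3e was at -0.72 in B cells and -1.19 in monocytes, and Lyz2 and Jchain were at -1.51 and -1.95 in B cells. Free RNA was not told apart as a source of these negative medians.

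For the higher cytotoxic genes in Glutoborin CD8 T cells, a few effector cells, NK cells within the class and free RNA of NK cells were weighed. NK cells are argued against: the Gzma change would need a share of 0.917% NK cells, but 20 other NK transcripts stood at 71.5 CPM in Vehicle and 68.5 CPM in Glutoborin, a change of -0.0294 (-0.118 to 0.0618) of the rise needed. Free RNA of NK cells is argued against as well, since Gzma in CD4 T cells had a log2 ratio of -0.68 (-1.08 to -0.29). Without the 10 cells of each library richest in the list, 6 members remained at least 1.5-fold higher, which leaves the list as a whole undecided by the bounds set. Ccl5 went from 0.98 over all cells to 1.24 (1.16 to 1.32) on 1748 and 5554 UMIs. Klrc1 went from 1.37 to 1.68 (1.08 to 2.33), Klrk1 from 1.30 to 1.47 and Gzmm from 0.73 to 0.81. This argues against the removed cells as the source of these rises. Gzmb fell from 2.40 to 1.34, S100a6 from 1.65 to 1.04 and Lgals1 from 0.72 to 0.32, so those cells may play a part there. Gzma was at 0.34 and Gzmk at -0.62 on 8 and 7 UMIs, values that a few effector cells may account for. A difference between the animals or libraries other than the treatment stays open, as does an effect of Glutoborin, which was not tested apart from it.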

How the results depend on the processing

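The alternatives chosen after the data were seen were the 25% mitochondrial limit, all T clusters together, lists without the 10 richest cells or without marker genes, and the mixed cycling cluster. Of the alternative values, 102 log2 share ratios stayed within their counting interval and 5 moved beyond it. These intervals are wide in small classes: type 1 dendritic cells stayed within theirs while turning from 0.63 to -0.35 with all variable genes, where no cluster was named type 2 dendritic cells, and to -0.14 at resolution 0.8. Their Vehicle and Glutoborin shares, 0.139% and 0.214%, were 1.65% and 1.30% with all variable genes and 1.602% and 1.45% at resolution 0.8. Gamma-delta T cells were 1.06% and 1.13% with doublets kept and 0.955% and 1.06% at resolution 0.8, and plasma cells 0.786% and 0.913% with genes centred within each library. Mature dendritic cells had no cluster of their own with doublets kept, genes centred, resolution 0.8 or the 25% limit. For the interferon lists, the CD8 cytotoxic list, the NK S phase and lipid lists and the monocyte cytokine list 99 medians stayed and 8 moved, for the other lists 649 stayed, 32 moved and 3 changed sign, for named genes 477 stayed and 39 moved, and 16 shares of cells with a UMI stayed. Most moves of named genes came with cells thinned to the same number of UMIs, where 25 moved and 61 stayed. The counts of list medians do not include thinning. With the 25% mitochondrial limit the log2 share ratio was 0.18 for CD4 and 0.22 for CD8 T cells and -1.06 for cells in no class, which were at -1.23 with resolution 0.8. With doublets kept it was -0.65 for T cells in no finer class. With all T clusters together the type I interferon median was -0.93 over the CD4 list members and -0.89 over the CD8 ones, and the interferon gamma median over the CD8 ones -0.53. Median-of-ratios scaling gave -0.73 for the type I list in CD8 T cells, and a minimum of 1 UMI gave -1.16 for the interferon gamma list in B cells. Without the 10 richest cells the NK S phase median was -1.74 and the monocyte interferon gamma median -0.72, and with the cells of the mixed cluster the NK S phase median was -0.86. The sign changed for oxidative phosphorylation in B cells with every cell weighted equally, at 0.0085, and for constitutive proteasome subunits in CD8 T cells under median-of-ratios scaling, at 0.0199, and without immunoglobulin, haemoglobin, mitochondrial and ribosomal genes in the total, at 0.0104. In each case the cause was not tested. No paired analysis was possible because each group has 1 library. Depth limits the smaller classes: in simulated regulatory T cells 26.0% of genes changed 1.5-fold had a bound beyond 1.2-fold.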

Other observations

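The values of the small classes and the tests of free RNA as a part of the difference, of uneven free RNA, of another difference between the libraries, of a few cycling cells and of the mixed cluster were chosen after the result was seen. Lower interferon-induced genes in Glutoborin extended to classes too small for the main comparison. In neutrophils, 22 Vehicle and 60 Glutoborin cells, the type I list had a median log2 ratio of -1.53 (-1.75 to -1.29) with 20 of 21 members at least 1.5-fold lower, and Ifit3 stood at 1155 CPM in Vehicle and 131 CPM in Glutoborin. The median was -1.05 in red pulp macrophages with 22 of 30 lower, including Oasl2 at -3.25 and Rsad2 at -2.97, -1.03 in type 2 dendritic cells with 39 of 44, -0.84 in plasmacytoid dendritic cells with 12 of 14, -0.79 in mature dendritic cells with 11 of 18, and -0.36 in plasma cells with 2 of 8. The unnamed clusters 15 and 16 were at -1.31 with 26 of 29 and -1.33 with 30 of 32.

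Type 2 dendritic cells, which present antigen to CD4 T cells, held more complement transcripts in Glutoborin. From 87 Vehicle and 108 Glutoborin cells, C1qa was at 3.25 (2.43 to 4.19), C1qb at 3.16 (2.44 to 3.98) and C1qc at 2.31 (1.45 to 3.29). The red cell uptake and iron handling list that holds them had a median of 0.86 with 7 of 12 members at least 1.5-fold higher. C1qa, C1qb, C1qc and several other members of this list are also markers of red pulp macrophages. How much of their UMIs lay in a few cells was not computed, and macrophages placed in this class were not tested. Transcripts of lymphocytes were lower in the same cells, with naive and memory T genes at -0.76 with 8 of 15 lower and B cell activation and germinal centre genes at -0.42 with 5 of 18 lower. G2 and M phase genes had a median of 1.00 (0.49 to 1.18) with 4 of 7 higher, including Mki67 at 2.00 on 19 and 85 UMIs, while heat shock genes were at -0.74 with 6 of 10 lower. In mature dendritic cells MHC class II genes had a median of 0.68 (0.48 to 0.70) with 5 of 9 higher.

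For the lower interferon-stimulated genes in Glutoborin, the median was -1.48 (-1.55 to -1.43) in B cells under 5% mitochondrial UMIs. This argues against kept B cells of 5% to 10% mitochondrial UMIs as the source. It cannot decide on damage or stress of other kinds, since kept B cells had median mitochondrial shares of 4.61% in Vehicle and 4.67% in Glutoborin. After the result was seen, monocytes were set beside CD4 T cells. The list stood at 27758 CPM in Vehicle and 18915 CPM in Glutoborin monocytes, against 10203 and 6537 CPM in CD4 T cells. Igkc stood at 873 and 616 CPM in monocytes, with 31.9% and 48.8% of it in 10 cells, against 602 and 270 CPM. More of the list was lost with less Igkc. This argues against 1 pool of free RNA, shared by both classes, as the whole difference in monocytes. In the other classes free RNA as the whole difference stays open. The variance between cells beyond counting error was 4.03 times as large in Vehicle B cells, 2.10 in CD4 and 1.73 in CD8 T cells. The limit of 2 was set for these classes together. The unevenness that B cells would need of free RNA was 2.495 times that of Lyz2, S100a8, S100a9 and Jchain, but 1.13 times without Lyz2. Of 44 members 9.09% took shares of the loss that differed beyond 2-fold between B and CD4 T cells. This fits free RNA but would also come from a shared response. List CPM lost per CPM of Igkc lost was 11.0 (10.2 to 12.1) in CD4 and 10.5 (9.67 to 11.5) in CD8 T cells. The whole Vehicle library held 1.602 list UMIs per Igkc UMI. Its barcodes at or over 10% mitochondrial UMIs held 10713.5 list CPM and 7725 Igkc CPM, mitochondrial UMIs left out. Free RNA of either make-up is argued against as the whole difference in CD4 and CD8 T cells. Free RNA of another make-up stays open, since its make-up was not measured. Free RNA may be a part of the difference, judged by Lyz2, S100a8, S100a9 and Jchain, which gave lower values than Igkc. The list CPM lost per CPM lost of these 4 transcripts differed between lymphocyte classes 1.498-fold (1.01 to 2.00) over all cells. Without the 10 cells richest in them it differed 1.28-fold (0.831 to 1.76). Igkc gave 3.08-fold (2.38 to 4.12) and 1.96-fold (1.46 to 2.70). The removal was chosen after 29.3% of the Igkc UMIs of Vehicle NK cells were found in 10 cells. The Igkc value over all cells goes against such a part, but the bounds set called for all of these values to do so. With 1 library per group, another difference between the animals or libraries cannot be told apart from the treatment.

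For the lower S phase genes in NK cells of Glutoborin, a few cycling cells, cycling NK cells placed in a mixed cluster and deeper cells in the Vehicle library were weighed. Without the 10 cells of each library richest in the list, which held 29.6% of its UMIs in Vehicle and 38.5% in Glutoborin, the median was -1.74 (-1.95 to -1.48), and with those of Vehicle alone removed, which favours this explanation, it was -0.80 (-0.90 to -0.60), so up to 10 cycling cells are argued against as the whole cause but not as a part. With the NK-like cells of the mixed cluster, 17 of 255 (6.67%) in Vehicle and 29 of 348 (8.33%) in Glutoborin, it was -0.86 (-0.95 to -0.73), which leaves room for a part of the difference there. With every cell thinned to the same depth it was -1.203 (-1.47 to -0.94), which argues against the greater weight of deeper cells in the sums. Thinning keeps each cell's expected share of S phase UMIs, so it cannot decide on differences between cells that go with depth. No biological explanation was tested, and a difference between the libraries other than the treatment stays open.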
